A study of Tetrahymena thermophila CU428 with 8 samples.

How the data were processed

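The series holds 8 ChIP-seq samples from the macronucleus of Tetrahymena thermophila, labelled as strain CU428, in 4 groups of 2, namely an input and a ChIP group for RPB7 and an input and a ChIP group for H3K4me2. Per the labels' protocols, RPB7 was precipitated from cells carrying an HA-tagged RPB7, from native chromatin cut with MNase. H3K4me2 was precipitated from wild-type cells after formaldehyde crosslinking and sonication, per the labels' protocols. The labels place all samples in growing cells.

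The values analysed were deposited raw counts, 1 column per antibody, over the same 252271 nucleosome positions of 148 bp on 966 scaffolds. Each table carries counting headers among its lines. Per the file headers, the RPB7 counts came from 1 paired-end alignment made with TopHat against the macronuclear genome, with unique mapping, a selected range of 120 to 260, and reads reduced to their centres. Per the file headers, the H3K4me2 counts came from 1 alignment made with Bowtie against the macronuclear genome, with unique mapping and a centre value of 100. The submitters' processing notes name TopHat2 and featureCounts, with no version. The genome build, the caller of the nucleosome positions and the library the positions were called from are not given in the sources used here. Coordinates are those of the deposited tables, with scaffold names as given there.

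The labels of both replicates of an antibody name the same table, and each table holds 1 column. Each header names 1 alignment, but whether a column holds 1 replicate or both pooled is not given in the sources used here. Each column was treated as 1 library of its ChIP group with no replicate number. The input groups were not analysed here. The tests fixed before the data were examined needed inputs and replicates, and were edgeR fits of ChIP against input, of the difference between the antibodies and of gene lists. They could not be run on 1 library per group, and the RPB7 and H3K4me2 libraries also differ in the cells (HA-tagged or wild type), preparation and aligner. The antibody cannot be told apart from these. All values below describe these 2 libraries, and no p-value is given. The reference table of gene symbols uses other sequence names than the deposited tables, so no position was assigned to a gene. The rule fixed beforehand for named genes could therefore not be used, and the regions named, the definitions of runs and arrays, and all alternatives were chosen after the values were seen. Regions named are the highest by total, by number of positions or by count.

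Counts were used without normalisation, and most comparisons between the libraries rest on ranks, on values within 1 library or on ratios to that library's median or mean. Raw counts at unequal depth enter the totals, the shares of positions with 0 counts, and the alternative that requires a mean of at least 50 counts over both libraries, in which H3K4me2 weighs more. A position was called high in a library when it ranked among the top 5% of positions. A run was a series of consecutive high positions with centre-to-centre steps of at most 500 bp. A regular position had steps of 180 to 220 bp on both sides. An array was a series of at least 8 positions with steps of at most 260 bp beside a gap, which was a step over 500 bp. A gap is a stretch with no called position, whatever its content. Long scaffolds held at least 300 positions and short scaffolds at most 30.

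Intervals on summary values are 95% ranges over 100 resamplings of whole scaffolds, and over 500 resamplings for the medians by place in an array. They describe the spread along the genome within a library, not the spread between replicates. Intervals on counts are exact 95% Poisson intervals, and the interval on a share of counts is a 95% Wilson binomial interval. Both cover counting error only and treat reads as independent. Reads without molecular identifiers are not independent molecules, so these intervals can be too narrow. The Wilson interval also takes the set of top positions as given, although the same counts chose it. A count of 0 at a position allows up to 3 counts, which is 0.237 per 1000000 RPB7 counts and 0.126 per 1000000 H3K4me2 counts. A single position that holds the median RPB7 count of 23 has a Poisson interval of 14.6 to 34.5. One that holds the median H3K4me2 count of 69 has an interval of 53.7 to 87.3. These are not intervals on the medians. Splitting each library's counts at random into equal parts gave a Spearman rho between the parts of 0.889 for RPB7 and 0.963 for H3K4me2.

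How the counts were made affects what they measure. Without an input, differences in nucleosome occupancy, DNA copy number and mappability remain in the counts. Unique mapping removes reads from repeated sequence. MNase cuts between nucleosomes, whereas sonicated fragments can span neighbouring positions, so the H3K4me2 counts of neighbours are smoothed to an unknown degree. Counting at called positions leaves out reads between them.

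The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated counts for the 252271 positions. Among seeded stretches of 8 positions, the search for runs recovered 14 at 2-fold, 139 at 4-fold and 198 at 8-fold, out of 200 at each size, with 1, 0 and 0 runs elsewhere. The simulated background had the same mean at all positions, the RPB7 median of 23. High positions of the RPB7 library held at least 160 counts, so these recoveries do not give the sensitivity in the libraries. A seeded Spearman rho of 0.3846 was recovered as 0.3851, and a seeded ratio of 1.5 between place 5 and place 1 of an array as 1.531. Alternatives changed the set of positions, the share of positions called high, the step within runs, the gap and the array length, and thinned the H3K4me2 counts to the RPB7 total.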

Results

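The study measured where RNA polymerase II (Pol II) and H3K4me2 lie along the chromatin of Tetrahymena thermophila, a ciliate that keeps a transcribed macronucleus beside a largely silent germline micronucleus. RPB7 is a subunit of Pol II. H3K4me2 is histone H3 dimethylated on lysine 4, a modification found on active chromatin in many eukaryotes. The RPB7 ChIP group and the H3K4me2 ChIP group were each represented by 1 column of counts, called a library here, which may hold 1 replicate or both pooled. The input groups were not analysed here. The RPB7 library held 12652983 counts at 252271 nucleosome positions, with a median of 23 per position and an interquartile range of 13 to 44. The H3K4me2 library held 23781879 counts, with a median of 69 and an interquartile range of 37 to 127. No difference described here has a replicate check.

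RPB7 counts were concentrated at few positions, some of them in stretches of neighbouring nucleosomes. The 1% of positions with the most counts held 20.5% of all RPB7 counts (Wilson interval 20.4% to 20.5%; 19.6% to 21.7% over resampled scaffolds). The same share of positions held 5.01% of the H3K4me2 counts (Wilson interval 5.00% to 5.02%; 4.88% to 5.13% over resampled scaffolds). The domain with the most RPB7 counts lay on scf_8254607 from 196453 to 202177, where 27 consecutive high positions averaged 1751 counts each, 76.1 times the genome median (Poisson interval of the mean 1736 to 1767). Its mean H3K4me2 count was 136, or 1.97 times the genome median. The run ended at a step over 500 bp, not at a fall below the cutoff. The next called positions, from 203062 to 204185, held 675, 507, 309 and 218 RPB7 counts.

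**Figure D1:**
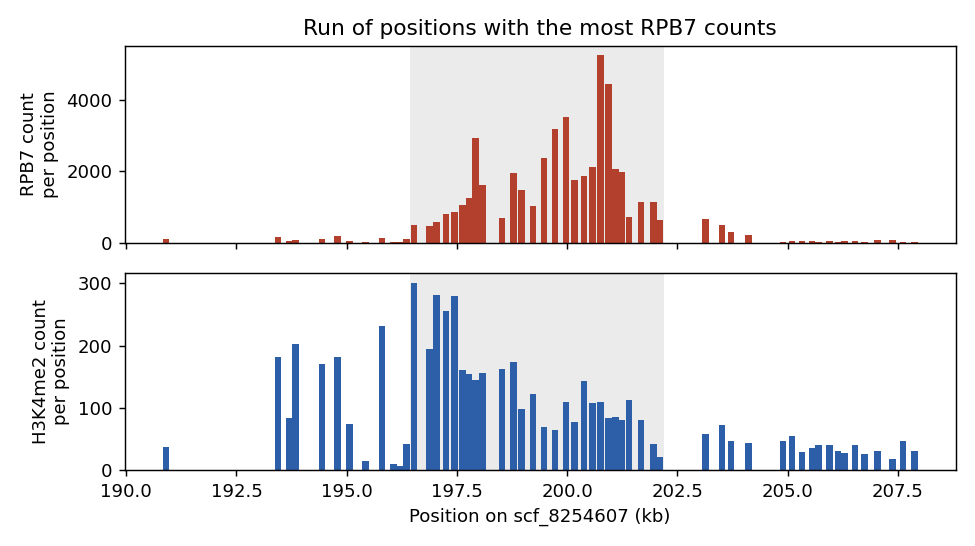
Counts per nucleosome position along scf_8254607 (x axis, kb), with RPB7 in the upper and H3K4me2 in the lower panel, 1 bar per position and the 27-position run shaded. RPB7 counts within the run reach 5239, while the highest H3K4me2 count, 301, stands at the left end of the run.

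Other domains were shorter. On scf_8254630, 12 positions from 314497 to 317115 had a higher mean, 2694 RPB7 counts (2664 to 2723). The 19 positions of scf_8254691 from 392950 to 396709 averaged 1693 (1674 to 1711), and the 18 positions of scf_8254475 from 459080 to 462526 averaged 1703 (1684 to 1723). H3K4me2 in these domains differed widely. Its mean was 122 on scf_8254630 and 96.2 on scf_8254475, but 46.4 on scf_8254691, which is 0.672 times the genome median (43.4 to 49.5 counts). Across the genome the 12614 high RPB7 positions, each with at least 160 counts, formed 6016 runs, of which 529 held 5 or more positions and 92 held 10 or more. Single positions made up 3468 of the runs (57.6%). The runs of 5 or more took in 31.4% of the high positions (29.0% to 33.2%). Shuffling the high positions 20 times gave at most 1 run of 5 or more in either library. Runs of 3 or more had a median length of 794 bp (interquartile range 577 to 1182.5 bp), 95% of them were no longer than 2262 bp, and the longest spanned 5725 bp. A step over 500 bp ends a run, and 18.3% of steps were that long. Run lengths in both libraries therefore depend on where positions were called.

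Most of the highest single RPB7 counts lay outside runs of 5 or more positions, though seldom among low neighbours. The position at 220424 to 220571 on scf_8254649 held 21962 counts (21672.5 to 22254.4), 955 times the median, and the higher of its neighbours held 856. On scf_8254284 the position at 177809 to 177956 held 12154, and on scf_8254665 that at 29132 to 29279 held 12142 with at most 109 counts in a neighbour. H3K4me2 at these positions was 74, 26 and 8 counts. Of the 10 positions with the most RPB7 counts, 3 lay inside runs of 5 or more. Among these 10, only the position on scf_8254665 had no neighbour above the cutoff of 160 counts. On scf_8254284 the higher neighbour held 909. Since run ends depend on where positions were called, lying outside a run of 5 or more does not show that a position stands alone.

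H3K4me2 counts were spread more evenly in these libraries and formed shorter runs. The preparations differed and no input was used, so background cannot be told apart from the mark here. Its highest count, 938 (878.9 to 1000), was 13.6 times its median. High H3K4me2 positions held at least 267 counts and formed 6713 runs, of which 232 held 5 or more positions and 0 held 10 or more. Runs of 3 or more had a median length of 570 bp (interquartile range 541 to 758 bp). The longest H3K4me2 runs held 9 positions, on scf_8254581 from 60787 to 62539 with a mean of 412 counts (399 to 425) and on scf_8254638 from 769934 to 771644 with a mean of 398 (385 to 411). Mean RPB7 counts there were 20.8 and 53.0. Runs of 5 or more held 10.1% of the high H3K4me2 positions (8.97% to 11.4%). That share was 3.45% when the top 2% of positions were called high, 18.0% for the top 10%, and 4.11% among positions with a mean of at least 50 counts.

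Similarity between positions fell with distance in both libraries and was higher for H3K4me2 at most distances. Neighbouring positions, a median of 220 bp apart, had a Spearman rho of 0.602 for RPB7 and 0.774 for H3K4me2. At a distance of 5 positions (median 1704 bp) the order was the opposite, with 0.428 for RPB7 and 0.386 for H3K4me2, and at 8 positions it was 0.342 and 0.326. The libraries were close at 10 positions (0.301 for H3K4me2 against 0.298 for RPB7), and H3K4me2 was higher at each longer distance computed. No interval was computed for these values, so small gaps between the libraries decide nothing. Random parts of a library had a rho of 0.889 for RPB7 and 0.963 for H3K4me2, so counting noise lowers RPB7 more. Sonicated fragments that span positions can raise H3K4me2 between neighbours. At 100 positions (median 38964 bp) both were low, at 0.0571 and 0.0830.

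**Figure D2:**
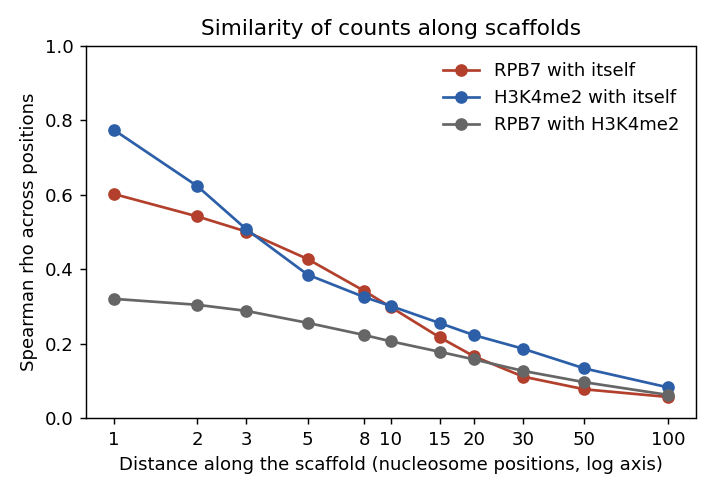
Spearman rho across positions (y axis) between counts at positions a given number of nucleosomes apart (x axis, log scale), for RPB7 with itself, H3K4me2 with itself and RPB7 with H3K4me2. H3K4me2 starts higher, at 0.774, and lies below RPB7 only at 5 and 8 positions, with 0.386 against 0.428 at 5.

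The counts of the 2 libraries were then compared position by position. Positions with more H3K4me2 counts had more RPB7 counts, with wide overlap. Neither library was set against an input. Nucleosome occupancy, DNA copy number and mappability that both share could give part of this relation, which was not tested. The median RPB7 count was 11 (quartiles 5 and 18) in the 10% of positions with the least H3K4me2 and 35 (quartiles 20 and 70) in the 10% with the most. Across the 252271 positions, which are not independent replicates, Spearman rho was 0.365 (0.350 to 0.378). In windows of 1, 5, 10 and 50 kb it was 0.432, 0.531, 0.598 and 0.770. On long scaffolds alone it was 0.319 across positions and 0.511 in windows of 50 kb. Among the 131239 positions with a mean of at least 50 counts over both libraries, rho was −0.222, against −0.428 when the H3K4me2 counts were shuffled over positions before the same selection.

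**Figure D3:**
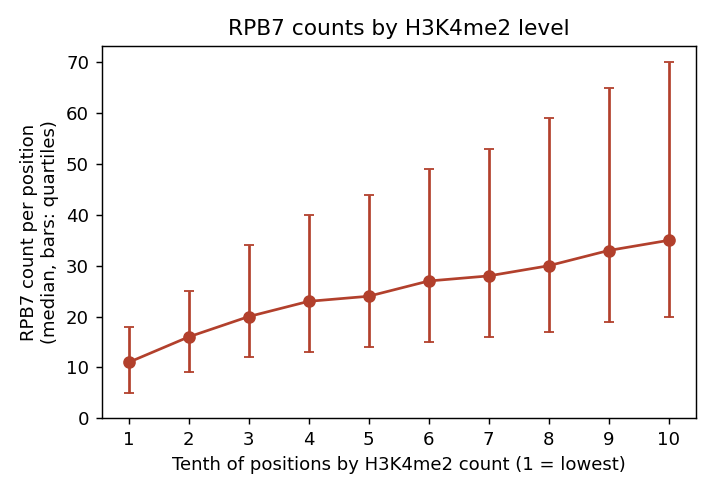
RPB7 count per position (y axis) for 10 bins of positions ordered by H3K4me2 count (x axis, 1 is lowest). Points are medians and bars run from the lower to the upper quartile. Ties were kept together, so bins held 23726 to 27034 positions. The median rises from 11 to 35 while the quartile ranges of neighbouring bins overlap.

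The positions highest in RPB7 were mostly not those highest in H3K4me2. Of the 12614 high positions of each library, 1232 (9.77%) were shared, against 631 for independent sets, a ratio of 1.95 (1.81 to 2.10). Sliding the RPB7 positions along the genome 1000 times gave 525 to 723 shared positions. Among positions with a mean of at least 50 counts the ratio was 1.02, against 0.535 when the H3K4me2 counts were shuffled over positions before the same selection. The median H3K4me2 count at all 12614 high RPB7 positions was 114, or 1.65 times the genome median of 69. It was 121 at the highest 2523 of them, 119 at the highest 1000, 102 at the highest 100 and 83 at the highest 10, or 1.20 times the genome median. Only 681 (5.40%) of the high RPB7 positions fell among the 25% of positions with the least H3K4me2. Without an input, variation in the DNA or chromatin that both libraries share enters these overlaps too.

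The runs of each library were then examined in the other library. Runs were chosen on a library's own counts, at least 160 for RPB7 and at least 267 for H3K4me2. Its own factor in its runs is therefore high by construction, and only the other library's factor describes a relation. The highest H3K4me2 count was 13.6 times its median, so the own factors of the libraries are not comparable. In the 529 RPB7 runs of 5 or more, the median of the run means was 17.1 times the genome median for RPB7 and 1.95 times for H3K4me2, and 47 runs (8.88%) had a mean H3K4me2 below the genome median. The excess is smaller against the genome means. The medians of the run means were 394 RPB7 and 134 H3K4me2 counts, and the genome means 50.2 and 94.3. In the 232 H3K4me2 runs the median of the run means was 5.20 times the genome median for H3K4me2 and 1.81 times for RPB7. For RPB7 this was 41.6 counts, below the genome mean of 50.2. Of these runs, 17.7% had a mean RPB7 below the genome median. Positions high in both libraries formed 804 runs, of which 102 held 3 or more positions. The longest, of 7 positions, lay on scf_8254823 from 371207 to 372591, with mean counts of 292 for RPB7 (279 to 305) and 359 for H3K4me2 (345 to 373), and on the 7-position scaffold scf_8254915. On scf_8254545, 6 positions from 23704 to 24837 averaged 651 RPB7 counts (630 to 671) and 379.5 H3K4me2 counts (364 to 395).

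Both libraries had more counts where nucleosomes were regularly spaced. The most frequent step between positions above the smallest one, 148 bp, was 197 bp. Regular positions, 34019 in number, had a median H3K4me2 count of 97 against 66 at other positions, a ratio of 1.47 (1.41 to 1.53). Their median RPB7 count was 29 against 23, a ratio of 1.26 (1.26 to 1.32). High H3K4me2 positions made up 10.5% of regular and 4.17% of other positions, and high RPB7 positions 6.72% and 4.76%. The H3K4me2 ratio was 1.95 in the 20% of positions with the least RPB7 and 1.04 in the 20% with the most. The RPB7 ratio was 1.31 in the 20% of positions with the least H3K4me2 and 1.07 and 0.971 in the 2 bins of 20% with the most, so the RPB7 excess at regular positions was absent where H3K4me2 was highest.

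In nucleosome arrays beside gaps over 500 bp, H3K4me2 was higher a few positions away from the gap, whereas RPB7 was highest next to it. In 4338 arrays of at least 8 positions, the median H3K4me2 count was 70 (67 to 72) at the position next to the gap and 105 (100 to 110) at place 5, a median of 782 bp further in. It was 77 (74 to 81) at place 8. The ratio of place 5 to place 1 was 1.5 (1.46 to 1.56) for H3K4me2 and 0.862 (0.830 to 0.913) for RPB7, whose medians were 29 and 25. The size of the H3K4me2 rise varied with the arrays chosen. The ratio was 1.27 in the 14589 arrays of at least 5 positions, 1.34 in 1000 arrays of at least 12, 1.16 in 289 of at least 16 and 1.13 in 111 of at least 20. The RPB7 ratio in arrays of these lengths ran from 0.821 to 0.929. With no array required the ratio was 1.17 for H3K4me2 and 1.00 for RPB7. With no array required the median H3K4me2 count was 60 next to the gap, 71 at place 4 and 68 at places 8 to 12. In arrays of at least 20 it varied between 41 and 51 with no clear maximum. How far the rise comes from choosing arrays was not tested. Sonicated fragments that span neighbouring positions may also shape the H3K4me2 medians beside a gap, which was not tested either. The preparations differed and no input was used, so the contrast between the libraries cannot be assigned to the antibodies.

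**Figure D4:**
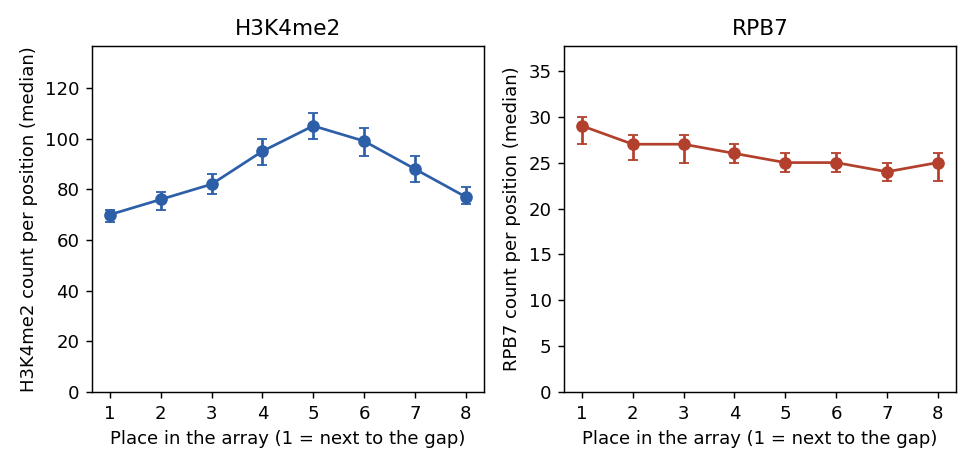
Median count per position (y axes) by place in the 4338 arrays of at least 8 positions beside a gap (x axis, 1 is next to the gap), with H3K4me2 on the left and RPB7 on the right; bars are 95% ranges over resampled scaffolds. H3K4me2 climbs from 70 to 105 at place 5 and returns to 77, and RPB7 goes from 29 to 25.

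Scaffolds differed in both libraries, and positions on short scaffolds more often had 0 counts for H3K4me2 than for RPB7. On the 538 scaffolds with at most 30 positions, which held 3433 positions, 57.5% of positions had 0 H3K4me2 counts and 15.0% had 0 RPB7 counts, with medians of 0 and 7. The mean count there was 0.104 of the genome mean for H3K4me2 and 0.214 for RPB7. The small scaffolds scf_8254915 and scf_8253895 supplied 25.1% of the H3K4me2 counts on these scaffolds. In the whole genome 2.80% of positions had 0 H3K4me2 counts and 0.926% had 0 RPB7 counts. Among the 206 long scaffolds, the median RPB7 count ran from 11 on scf_8253908 to 52 on scf_8254457, and the median H3K4me2 count from 12 on scf_8254674 to 120 on scf_8254194. The low extremes were low in both, with a median H3K4me2 count of 13 on scf_8253908 and a median RPB7 count of 14 on scf_8254674. Of the high extremes, scf_8254457 was high in both, with a median H3K4me2 count of 106, whereas scf_8254194 had a median RPB7 count of 28 against the genome median of 23.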

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

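All alternatives here were chosen after the data were seen. No paired analysis was possible because each antibody had 1 column with no replicate number. For the same reason none of the alternatives planned beforehand was run: other normalisations, DESeq2, low-count filters in the fits, leaving out replicates, the block, pooled fits, fold thresholds, gene length and other gene list tests. Of 84 alternative values, 46 moved by less than their interval, 37 moved by more without reversing and 1 reversed. A count of 0 at a position allows up to 3 counts. No summary moved beyond its interval when H3K4me2 was thinned to the RPB7 total.

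Requiring a mean of at least 50 counts left 131239 positions. It reversed rho from 0.365 to −0.222, which the selection on the sum of both libraries favours, since shuffled counts gave −0.428. It brought the overlap ratio to 1.02, against 0.535 for shuffled counts. It also brought the top 1% share to 17.7% for RPB7 and 3.51% for H3K4me2, H3K4me2 runs to 4.11%, and the ratios of regular to other positions to 1.08 for RPB7 and 1.32 for H3K4me2. For the other moves, here and below, the cause was not tested. On scaffolds with at least 300 positions, the H3K4me2 top share was 4.79%, rho 0.319 and the regular ratios 1.25 for RPB7 and 1.40 for H3K4me2. With at least 1 count in both libraries, the H3K4me2 top share was 4.88% and rho 0.328. Without the 100 highest positions, the RPB7 top share was 18.2%. Without abutting positions, the H3K4me2 top share was 4.87%, rho 0.346, the overlap ratio 1.72, runs 21% for RPB7 and 7.37% for H3K4me2, the RPB7 regular ratio 1.25, and place 5 over place 1 0.933 for RPB7 and 1.64 for H3K4me2.

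With the top 2% of positions, the overlap ratio was 1.79 and runs held 28.2% of RPB7 and 3.45% of H3K4me2 positions; with the top 10% they held 34.6% and 18.0%. With steps of at most 300 bp, runs held 23.0% and 8.91%, and with 1000 bp RPB7 runs held 40%. Place 5 over place 1 for H3K4me2 was 1.59 beside gaps over 800 bp, 1.45 on the left side only, and 1.34, 1.16 and 1.13 in arrays of 12, 16 and 20. With no array required it was 1.17, and 1.00 for RPB7, which was 0.821 in arrays of 12.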

Other observations

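All tests in this part were chosen after the results were seen, except the test of whether H3K4me2 lay toward one end of RPB7 runs, whose bound was set before its value was seen, though on runs defined after the counts were seen.

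Around the highest position of the 529 RPB7 runs of 5 or more, RPB7 fell on both sides over about 10 positions. A fall from a library's own maxima follows from choosing them, so only its width is described here. The median was 667 counts at the maximum, 302.5 and 291 at 2 positions to either side, 189 and 173.5 at 5, 70.5 and 70 at 10, and 35 and 33 at 20. H3K4me2 around the same positions fell from 131 to 110 and 111.5 at 5 positions, and was 87.5 and 88 at 20, still above the genome median of 69. Around the maxima of the 232 H3K4me2 runs, H3K4me2 fell from 431 to 304 and 284 at 2 positions and to 123 and 104 at 5. RPB7 there was 39 at the maximum and 30 and 31 at 5 positions.

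A hypothesis was that H3K4me2 lies toward one end of RPB7 domains rather than evenly over them, as it would if the mark sat at one end of transcribed genes. The median absolute log2 ratio of H3K4me2 between the left and right parts of the 529 runs was 0.641, above the range of 0.475 to 0.585 (95%) in 1000 sets of random windows matched on number of positions and H3K4me2 level. The excess over random windows is what the hypothesis predicts. The ratio has no sign, however, and also rises with other unevenness of H3K4me2 within a run, so it does not single out a mark at one end of genes. Gene positions and strand were not used here, and the direction along genes is open. A related idea was that H3K4me2 domains sit just outside the edges of RPB7 runs. High H3K4me2 positions were not denser there. They made up 8.26% of positions within 3 outside an edge and 10.9% inside, a ratio of 0.759, and 5.00% of all positions. Runs also end at steps over 500 bp, so positions just outside can still be high in RPB7, as on scf_8254607. The comparison scored single positions rather than H3K4me2 runs, so it does not decide the idea.

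Positions on short scaffolds more often had 0 counts for H3K4me2 (57.5%) than for RPB7 (15.0%). Lower depth of the H3K4me2 library and loss of reads near scaffold ends are argued against, by its total of 1.88 times the RPB7 total and by a median within 1 kb of the ends of long scaffolds of 0.795 of their median (0.685 to 0.918). Fewer uniquely mapping reads in the H3K4me2 alignment may account for it. Of the positions with 0 H3K4me2 counts, 10.1% on long and 4.97% on short scaffolds had more RPB7 counts than the genome median of 23, and those on long scaffolds had a median RPB7 count of 9, so most were low in RPB7 too. Without sequence, mapping cannot be told apart from a lack of the mark, and no biological explanation was tested.

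The small scaffolds scf_8254915 (7 positions) and scf_8253895 (4 positions) held the highest mean H3K4me2 counts. Their median H3K4me2 counts were 876 and 664, or 12.7 and 9.62 times the genome median, and their median RPB7 counts 234 and 211.5, or 10.2 and 9.20 times. More copies of this DNA, or several copies under 1 name, may account for the excess in both libraries, since the RPB7 factor was 0.801 and 0.956 of the H3K4me2 factor. A true excess of both Pol II and the mark would give the same values and was not tested, and no input was used here.

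The 10 positions with the most RPB7 counts stood 242 to 955 times above the median. Extra copies of the DNA that are counted alike in both libraries are argued against. The H3K4me2 count over its median was 0.00323 of the same RPB7 factor at the median position and at most 0.0106. Copies only in the HA-tagged cells, without the mark, or lost in the H3K4me2 alignment would also leave H3K4me2 low. They remain open, since no input was used here. Duplicated fragments from 1 site could give such spikes. The ratio of the count to that of the higher neighbour had a median of 8.68 and ran from 1.29 to 111 over the 10 positions. Counts without molecular identifiers leave duplication and dense Pol II at 1 site open, and these cannot be told apart here. No biological explanation was tested.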
